A study of Rattus norvegicus with 19 samples.

How the data were processed

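Gene expression was measured on 19 Illumina rat arrays, each hybridized with biotin-labelled cRNA made from total RNA of trigeminal nerve tissue. The samples were 12 malignant peripheral nerve sheath tumours (MPNST), 1 microtumour and 6 pools of untreated nerves. Tumours had been induced with N-ethyl-N-nitrosourea (ENU), an alkylating carcinogen, given at 80 µg per g body weight on postnatal day 1. Each tumour array held a single tumour, whereas each nerve array held RNA pooled from animals 85 days old, so the spread between nerve arrays is a spread between pools. The treatment text of the nerve samples also mentions ENU, but their own tag reads untreated and they were taken as untreated.

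The authors read the arrays with BeadStudio 3.0. The deposited raw table gives, per the file headers, the average bead signal of each probe as an intensity, neither normalized nor background subtracted, and a detection p-value against negative control beads for each intensity. The authors also deposited a table of intensity values after background subtraction and scaling. Set against the raw signals, each column of that table was a straight-line function of a raw column, with a largest residual of 0.0145 intensity units. By this check 17 of the 19 columns matched the raw column of the same sample, and the other 2, nerve 5 and nerve 6, matched each other's. Both are BDIV pools of different sex, each table was used with its own labels, and a fit with the signals of both pools exchanged was run for the sex comparison. The labels allow no independent check of sex, because no probe on the array was named for Xist or a Y-linked gene. A deposited table of averages over the nerve arrays was not used, since the other tables give these arrays individually.

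Raw intensities were background corrected, quantile normalized and put on a log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16 and with the background estimated from the detection p-values. The offset draws dim values together, so a fold against a dim value is smaller than the ratio of background-subtracted signals. Of 21791 probes, 11816 had a detection p-value under 0.05 on at least 6 of the 19 arrays and were kept. Where a symbol had several probes, the one with the highest mean was used, which left 11796 features, 8575 of them with a gene symbol. The array annotation gave 1 symbol for 13387 probes and none for 8404. Chromosomes were taken by gene symbol from RefSeq genes of the GRCr8 assembly and no positions are given, because the files name no genome build.

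Groups were compared with limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. MPNST, microtumour and nerve each had a coefficient in a fit of all 19 arrays, with 16 residual degrees of freedom. The single microtumour was assumed to vary like the other arrays. Sex was tested in the MPNST and in the nerve pools with strain as a covariate, and strain in each tissue with sex as a covariate. The strain test in MPNST was an F test over BDIV, BDIX and their F1 hybrid, in which the single tumour of the congenic strain BDIX.BDIV-Mss4a kept its own coefficient. The differences between tissues were compared between sexes and between BDIV and BDIX with interaction terms. Nerve 5 and nerve 6 stayed separate arrays, and a fit with both averaged was an alternative.

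The tests, the covariates, 28 gene lists, the rule for naming genes and the main alternatives were fixed before the data were examined. The lists cover cell types of nerve and tumour, other cell types that the tissue could hold, and pathways. The 22 lists with at least 5 measured members were tested with limma's camera at an inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and limma's fry were alternatives. Named for MPNST against nerve were the 12 highest and 12 lowest called genes whose MPNST arrays all lay beyond all nerve arrays, up to 2 rising and 2 falling called members of each list, and a fixed set of 12 genes. The other comparisons name up to 5 rising and 5 falling called genes. Provisional symbols were left out of the rule.

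The place of each array between the tissues was computed for genes called with a difference of at least 1 on the log2 scale, as 0 at the nerve mean and 1 at the MPNST mean. For nerve and MPNST arrays the genes and both means were taken from the other arrays.

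For arrays, their number limits the precision. Tested on simulated data with 200 changed features, the fit of MPNST against nerve found 80.6% of changes of 0.5, 92.5% of changes of 1 and 100% of changes of 2 on the log2 scale. The fits of the microtumour found 52.2% against nerve and 56.7% against MPNST of changes of 1. For sex the shares at a change of 1 were 83.6% in MPNST and 79.1% in nerve. For the strain comparisons they were 74.6% for BDIV against BDIX nerve, 71.6% for congenic against BDIX nerve and 61.2% for MPNST. False calls made up 3.68% to 8.06% of the calls in these simulations. The simulated noise was drawn independently for each feature and array, without technical differences between groups of arrays. The shares therefore do not allow for such differences or for genes that vary together.

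Alternatives were the authors' values, no background correction, median scaling, an offset of 50, no detection filter or a stricter one, every probe on its own, array weights, an intensity trend with robust estimation, covariates, subsets by strain, a replicate block, a minimum difference of 1, and leaving out each array in turn. Arrays in separate background ranges were seen only in the data, so a batch block, fits within each range and the fits on nerve 5 and nerve 6 were added after seeing the data. A block for the chip was not run, since the files name no chip. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.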

Results

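Expression profiles were collected from rat trigeminal nerve tumours induced with ENU and from untreated trigeminal nerves. The 12 MPNST comprised 7 from F1 hybrids of BDIV and BDIX, 2 from BDIX, 2 from BDIV and 1 from the congenic strain BDIX.BDIV-Mss4a, with 6 males and 6 females. The microtumour came from a male of the congenic strain. The 6 nerve pools were 1 male and 1 female pool each of the congenic strain, BDIX and BDIV, so F1 hybrids had no nerve pool. Between 44.1% and 54.1% of the probes were detected on each array, and the median raw signal ranged from 80.8 to 109. The arrays fell into separate ranges of background. The 25th percentile of raw signal was 80.4 to 94.6 on 11 arrays (9 MPNST and 2 nerve pools, the congenic ones) and 59.0 to 67.5 on 8 arrays (3 MPNST, the microtumour and 4 nerve pools); these are called the high-background and the low-background arrays. With the tissue groups held constant, 3108 of the 11796 features differed between the ranges.

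The comparison of MPNST with nerve asked how the expression of the tumours differs from that of the tissue they grow in. Aard (chromosome 7) rose 37.9-fold, by 5.24 ± 0.24 on the log2 scale (SE, 12 MPNST and 6 nerve pools). Vcan, a large matrix proteoglycan, rose by 4.84 ± 0.25, and Postn, a secreted matrix protein, by 4.45 ± 0.43; both lie on chromosome 2. The mitotic genes Ccnb2, Cdk1, Prc1 and Cks2 rose between 10.99-fold and 15.98-fold. Also among the 12 highest were Adamts1, a secreted protease (15.6-fold), Itga1, an integrin subunit (12.9-fold), Lpar4, a lysophosphatidic acid receptor (10.9-fold), Ccnd1, the G1 cyclin (10.6-fold), and Arhgap11a (10.6-fold).

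Among the 12 lowest genes, Mal, a myelin proteolipid, was 51.8-fold lower, a difference of -5.69 ± 0.39 on the log2 scale. Tac1, the precursor of substance P, was 32.9-fold lower (-5.04 ± 0.28). The intermediate filament genes Nefl and Prph were 27.8-fold and 25.4-fold lower, the sodium channel gene Scn10a 23.0-fold, and the nerve terminal gene Snap25 29.2-fold. Kcnk1, Stmn2, Sncg, Pcp4, Stmn3 and Maob were the others, between 23.8-fold and 30.5-fold lower. Of the 12 MPNST, Tac1 and Snap25 were detected in 8, Kcnk1, Stmn2 and Stmn3 in 9, Nefl in 10 and Mal, Pcp4 and Prph in 11. Adjusted p-values of the 24 genes lay between 1.89e-12 for Kcnk1 and 0.000229 for Nefl. The level of Nefl varied most in the tumours, with an SD of 2.14 on the log2 scale against 0.27 in nerve.

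**Figure D1:**
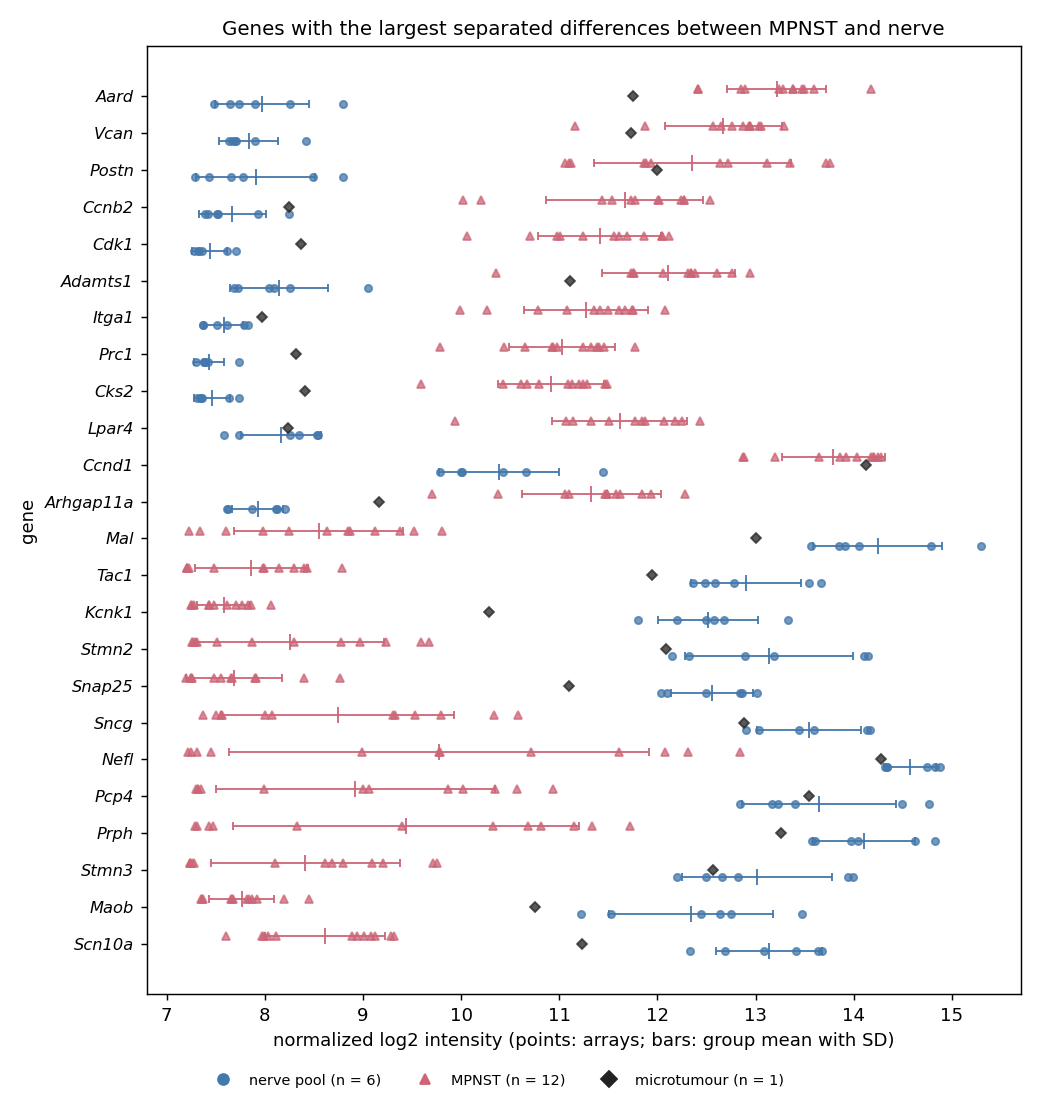
Normalized log2 intensity of the 12 genes with the highest and the 12 with the lowest difference between MPNST and nerve, chosen among genes whose groups do not overlap. Points are arrays, bars are group means with SD (12 MPNST, 6 nerve pools), and diamonds are the single microtumour, which lies at 14.13 for Ccnd1 and at 8.25 for Ccnb2.

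In all, 2906 features were higher and 2453 lower in MPNST, together 45.4% of the 11796 tested. Of these, 666 were higher and 777 lower by at least 2-fold. All MPNST lay above all nerve pools for 978 of the higher features and below them for 1013 of the lower ones, where chance separates 0.0108% of features. With median scaling in place of quantiles, 1399 features were higher and 3081 lower, so that the share of calls that were higher was 31.2% in place of 54.2%, although no call of either direction was reversed. The sign held within the high-background arrays for 99.6% and within the low-background arrays for 99.8% of the called features, and with batch as a block 2981 were higher and 2446 lower.

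Among the genes fixed beforehand, the Schwann cell and receptor genes went different ways. Erbb3, a neuregulin receptor, rose by 1.36 ± 0.27 and Sox10, a transcription factor of the Schwann cell lineage, by 1.11 ± 0.27 on the log2 scale. Between tumours and pools of the same strain, Sox10 differed by 1.88 in BDIV but by 0.41 in BDIX. Its level was 10.38 and 10.34 in the BDIV pools and 11.71 to 12.33 in the other pools, against 11.89 to 12.93 in the MPNST. S100b, a Schwann cell marker, fell by 2.43 ± 0.41. Within the high-background and the low-background arrays the differences were 0.98 and 1.94 for Erbb3 and -2.89 and -1.45 for S100b. Erbb2 rose by 0.19 ± 0.04 from a level near the background, and did not pass the test with median scaling (0.12). Nf1 differed by 0.03 ± 0.02 (limma adjusted p = 0.208) and Ngfr by 0.46 ± 0.71 (adjusted p = 0.623), with a difference for Ngfr of -0.30 when batch was a block; neither passed the test. The probes for Egfr and Nf2 were not detected on enough arrays to be tested, and Cdkn2a and Mki67 had no probe under their symbol.

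The gene lists were compared to see which cell types and processes moved together, and 5 of the 22 tested lists were higher and 5 lower in MPNST. Cell cycle genes were the most uniform: 34 of 35 measured members rose, also 34 when adjusted over the list alone, with a median of 1.45 on the log2 scale (camera adjusted p = 1.27e-13; adjusted p = 0.310 with an estimated correlation). MAPK output genes rose in 8 of 16 members, also 8 adjusted over the list alone, led by Ccnd1 and by Dusp6, a phosphatase induced by ERK (5.54-fold). Their shift (median 0.53, camera adjusted p = 0.0015) was the only one kept with an estimated correlation (adjusted p = 0.0353). That correlation was -0.03 for this list and between 0.25 (extracellular matrix) and 0.63 (cell cycle) for the other shifted lists. A higher correlation makes the test stricter, but the adjusted p-value with it was larger for every shifted list, MAPK output included. Of 20 extracellular matrix genes, 11 rose, among them Postn and Col18a1 (9.41-fold), and 3 fell, among them Spp1 (5.07-fold lower) and Dcn (2.90-fold lower); 14 changed when adjusted over the list alone (median 1.09, camera adjusted p = 0.0234; adjusted p = 0.509 with an estimated correlation). Macrophage genes rose in 11 of 18 members, also 11 adjusted over the list alone, with the complement genes C1qc (5.30-fold) and C1qb (4.98-fold) highest (median 0.49, camera adjusted p = 0.00114; adjusted p = 0.455 with an estimated correlation). MHC and antigen presentation genes rose in 9 of 12 members, also 9 adjusted over the list alone, with RT1-Ba (3.19-fold) and RT1-DMb (2.87-fold) highest (median 0.81, camera adjusted p = 0.00175; adjusted p = 0.318 with an estimated correlation).

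Sensory neuron genes fell in 14 of 17 members, also 14 adjusted over the list alone, with Tac1 and Stmn2 lowest (median -3.64, camera adjusted p = 3.78e-11; adjusted p = 0.246 with an estimated correlation). Genes of myelin and myelinating Schwann cells fell in 11 of 14, also 11 adjusted over the list alone, with Mal and Mbp (20.7-fold lower) lowest (median -2.03, camera adjusted p = 3.49e-07; adjusted p = 0.249 with an estimated correlation). Of 16 cholesterol synthesis genes, 12 fell, Fdft1 (5.35-fold) and Idi1 (3.9996-fold) most, and 1 rose, Ebp (1.40-fold); 13 changed when adjusted over the list alone (median -1.26, camera adjusted p = 2.72e-05; adjusted p = 0.310 with an estimated correlation). Mitochondrial respiratory chain genes fell in 9 of 27 members, 6 when adjusted over the list alone, with Ndufa10 and Ndufs1 lowest (median -0.16, camera adjusted p = 0.0228; adjusted p = 0.548 with an estimated correlation). Astrocyte and oligodendrocyte genes fell in 5 of 9 members, also 5 adjusted over the list alone, with Ermn (3.04-fold, detected in 6 of 12 MPNST) and Mobp (1.85-fold, detected in 3) lowest (median -0.67, camera adjusted p = 0.0476; adjusted p = 0.488 with an estimated correlation). Within the high-background and the low-background arrays the median was -0.63 and -1.78 for the cholesterol synthesis list, with -0.65 and -2.76 for Idi1 and 1.02 and 0.13 for Ebp; it was -0.06 and -0.17 for the mitochondrial and -0.86 and -0.48 for the astrocyte list. The astrocyte list lay at 0.86 in nerve 2 and 0.43 in nerve 5 relative to the nerve mean, and at -0.55 to -0.16 in the other 4 pools, close to the -0.75 to -0.18 of the MPNST; Mobp was at 8.99 and 9.38 in those pools and at most 7.87 on the other nerve and MPNST arrays. For the mitochondrial list all 12 MPNST (-0.42 to -0.02) lay within the range of the pools (-0.61 in nerve 4 to 0.36 in nerve 5). The astrocyte, mitochondrial and extracellular matrix shifts did not pass the test with sex and strain as covariates, where their medians were -0.47, -0.12 and 0.74, or with only the strains that have nerve pools (-0.18, -0.11 and 0.69). The astrocyte shift did not pass within either background range, the mitochondrial shift not within the high-background arrays or with the authors' values (-0.21), and the extracellular matrix shift not within the low-background arrays (1.28), and leaving out 1 array ended the astrocyte shift in 8 and the mitochondrial shift in 2 of 18 fits.

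**Figure D2:**
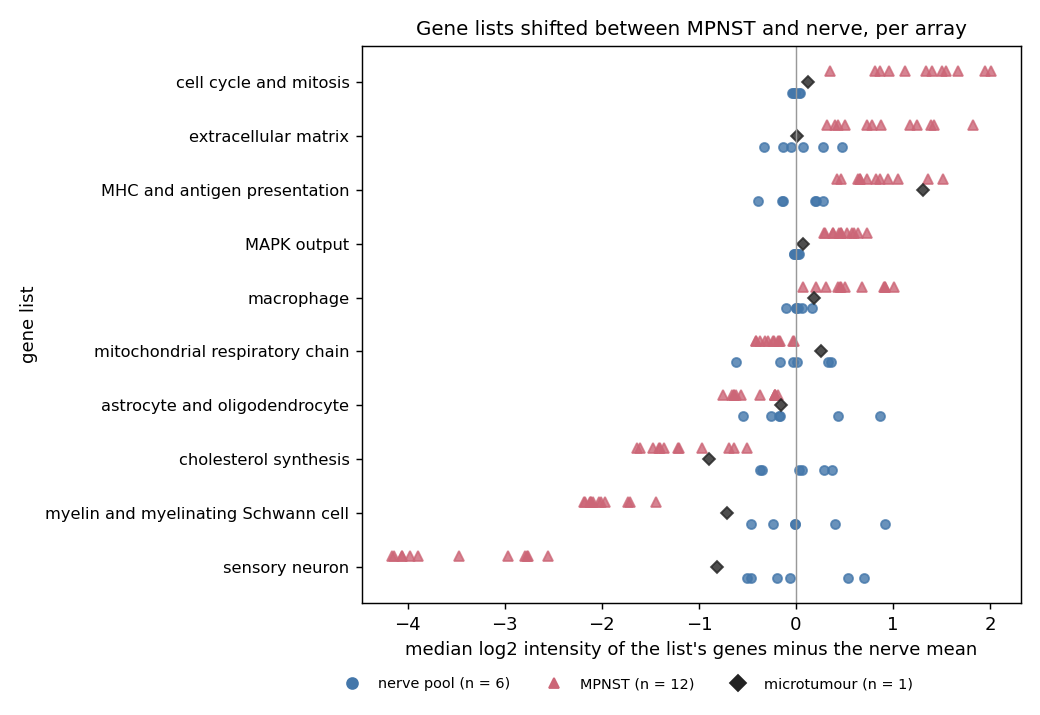
Median log2 intensity of the measured genes of each shifted list minus the nerve mean, for each array. The 12 MPNST lie between -4.16 and -2.56 for the sensory neuron list and at 0.35 or above for the cell cycle list, apart from the 6 nerve pools in both.

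The other 12 tested lists were not shifted, with camera adjusted p-values from 0.0801 to 0.936, although single members passed the test; the members of 1 of them are left out. Fibroblast genes changed in 6 of 9 members, also 6 adjusted over the list alone: Mfap5 fell 7.43-fold (detected in 10 of 12 MPNST) and Gsn 3.37-fold, and Dpt rose 1.66-fold. Of 10 endothelial genes 8 changed, also 8 adjusted over the list alone, in both directions; Angpt2, a vessel remodelling factor, rose 7.95-fold and Plvap 2.27-fold, and Cldn5, a tight junction gene, fell 2.82-fold and Vwf 2.65-fold. Of 21 immature Schwann cell and neural crest genes 10 changed, also 10 adjusted over the list alone; Ets1 (3.05-fold) and Sox2 (2.72-fold) rose most, and S100b (5.40-fold) and Dhh (3.35-fold) fell most. Among 16 glycolysis and hypoxia genes 7 changed, also 7 adjusted over the list alone: Pfkp (7.80-fold) and Ndrg1 (7.09-fold) fell most, and Ankrd37 (1.66-fold) and Pdk1 (1.35-fold) rose. Immediate early genes rose in 6 and fell in 1 of 11 members, 7 adjusted over the list alone, with Ier2 (2.70-fold) and Zfp36 (2.68-fold) highest and Dusp1 (2.19-fold) lower. Matrix proteases and inhibitors rose in 6 and fell in 2 of 16, 8 adjusted over the list alone; Adamts1 and Plat (3.35-fold) rose most, and Timp2 (1.64-fold) and Ctsb (1.56-fold) fell. Receptors, Ras pathway genes and tumour suppressors rose in 5 and fell in 2 of 13, 7 adjusted over the list alone; Erbb3 and Nras (1.84-fold) rose most, and Cdkn1b (3.24-fold) fell most. In the interferon response list 2 of 12 members rose, also 2 adjusted over the list alone, Irf1 (2.69-fold) and Gbp2 (1.87-fold). Adipocyte genes fell in 4 of 8 members, also 4 adjusted over the list alone, with Lpl (2.36-fold) and Pnpla2 (2.09-fold) lowest. None of the 10 skeletal muscle genes and none of the 9 T and NK cell genes passed the test.

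The 6 lists with fewer than 5 measured members were not tested as lists. All 4 perineurial genes fell, also 4 adjusted over the list alone, Itgb4 (4.18-fold) and Tjp1 (1.58-fold) among them, but Tjp1 was 0.33 higher in BDIV tumours than in BDIV pools on the log2 scale and 1.10 lower in BDIX tumours than in BDIX pools. Of 4 red blood cell genes 2 fell, also 2 adjusted over the list alone, Hbb-b1 (6.28-fold) and Hbb (4.30-fold). Between the means of tumours and pools of the same strain, Hbb-b1 differed by -0.13 in BDIV and -2.84 in BDIX. Of the genes named above, Dcn (-0.32 and -1.99) and Gsn (-0.49 and -2.39) also fell less in BDIV. Of 4 pericyte and smooth muscle genes 2 rose, also 2 adjusted over the list alone, Cspg4 (3.13-fold) and Tagln (2.09-fold). Of 2 melanocyte genes 1 fell, also 1 adjusted over the list alone, Tyrp1 (7.14-fold, detected in 7 of 12 MPNST). Both mast cell genes, Cma1 and Kit, fell by 0.10 and 0.09 on the log2 scale from levels near the background (each detected in 2 of 12 MPNST and 5 of 6 pools), also 2 adjusted over the list alone, and the 1 measured B and plasma cell gene did not pass the test. With median scaling Ebp, Dpt, Pdk1, Gbp2, Cspg4, Tagln and Nras did not pass the test, and with batch as a block Cspg4, Tagln, Kit and Timp2 did not. On the log2 scale the block moved Cspg4 from 1.65 to 1.35, Tagln from 1.06 to 0.93, Kit from -0.09 to -0.06 and Timp2 from -0.71 to -0.63. Leaving out 1 of the 18 arrays in turn ended the call of Dpt in 13 fits, of Pdk1 and Cspg4 in 12, of Tagln in 9, of Ebp and Kit in 3 and of Timp2 in 1. Within the high-background and the low-background arrays the differences on the log2 scale were also apart, with the same sign, for Lpl (-0.87 and -1.85), Plvap (1.28 and 0.75), Dcn (-1.73 and -0.86), Gsn (-2.45 and -1.48), Sox2 (1.23 and 1.90), Zfp36 (0.83 and 1.43), Cma1 (-0.02 and -0.15), Kit (-0.02 and -0.09), Timp2 (-0.93 and -0.34), RT1-Ba (0.92 and 2.38), Tagln (0.54 and 1.30), Tjp1 (-0.87 and -0.36) and Hbb (-2.99 and -1.74).

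The microtumour was compared with nerve and with MPNST to place it between them. Of 12 sensory neuron genes that passed the test between the tissues with a difference of at least 1 on the log2 scale, 1 lay nearer the MPNST mean than the nerve mean in the microtumour, and of 12 extracellular matrix genes 5 did. The single microtumour has no spread of its own, so each SE and test here takes its spread from the nerve pools and the MPNST. Compared with nerve, Pcdh20, a protocadherin, rose 30.6-fold (4.93 ± 0.90 on the log2 scale, 1 microtumour and 6 pools), Postn 17.0-fold, Vcan 14.8-fold, Igfbp3 14.0-fold and Aard 13.8-fold. Lower than in nerve were Akr1c12 (16.04-fold, at a level of 7.28 in the microtumour that was detected but near the background), Mbp (15.1-fold), Mgll (11.3-fold), Spock2 (10.4-fold) and Camk2g (6.44-fold). Compared with the 12 MPNST, Mal was 22.03-fold higher (4.46 ± 0.81), and the neuronal genes Stmn3, Sncg, Tac1 and Stmn2 were 14.2-fold to 17.8-fold higher. Mitotic Ccnb2 (10.7-fold) and Cdk1 (8.22-fold) were lower, as were Lpar4 (10.4-fold), Itga1 (9.80-fold) and Akr1c12 (9.78-fold). Pcdh20 was detected in 3 and Igfbp3 in 4 of the 6 pools, and Tac1 in 8, Stmn2 and Stmn3 in 9 and Mal in 11 of the 12 MPNST. The microtumour's level of Ccnd1, 14.13 on the log2 scale, lay within the MPNST (mean 13.79, SD 0.53). By limma's test 216 features were higher and 143 lower than in nerve, and 203 were higher and 118 lower than in MPNST. These totals of 359 and 321 depended on the processing. Against nerve 547 features differed with median scaling and 599 with batch as a block, and against MPNST 740 with median scaling, 712 with the authors' values, 600 with array weights and 559 with sex and strain as covariates. Within the low-background arrays, which hold the microtumour, 146 and 186 features differed, with Pcdh20, Postn and Mgll against nerve and Lpar4 and Itga1 against MPNST the named genes that passed. With the authors' values Mbp and Spock2 against nerve and Mal, Stmn3, Sncg, Tac1, Stmn2 and Cdk1 against MPNST did not pass the test, and leaving out 1 MPNST ended the call of Sncg in 3 and of Akr1c12 in 4 of 12 fits.

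On a scale of 0 at the nerve mean and 1 at the MPNST mean, the median gene of the microtumour lay at 0.52. The nerve pools lay between -0.09 and 0.13 and the MPNST between 0.88 and 1.08. Cell cycle genes of the microtumour lay near nerve (median 0.12 over 20 genes), as did sensory neuron genes (0.20 over 12) and endothelial genes (0.21 over 5). Extracellular matrix genes lay at 0.37 (12 genes), myelin genes at 0.50 (8), cholesterol synthesis genes at 0.56 (9), immature Schwann cell genes at 0.80 (6), macrophage genes at 0.94 (8) and MHC genes at 1.74 (5). These are only the members that passed the test with a difference of at least 1, and over all measured members some lists lay elsewhere. The microtumour's median over all members was 0.01 above the nerve mean on the log2 scale for extracellular matrix (nerve pools -0.33 to 0.48, MPNST 0.32 to 1.82), 0.06 for immature Schwann cell genes (nerve pools -0.09 to 0.12, MPNST -0.04 to 0.56) and 0.18 for macrophage genes (nerve pools -0.10 to 0.17, MPNST 0.07 to 1.01). For MHC genes it was 1.31, within the MPNST (0.43 to 1.52). For cholesterol synthesis genes it was -0.90, also within the MPNST (-1.63 to -0.50), with the nerve pools at -0.37 to 0.37. These places are values of a single array and carry no test.

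**Figure D3:**
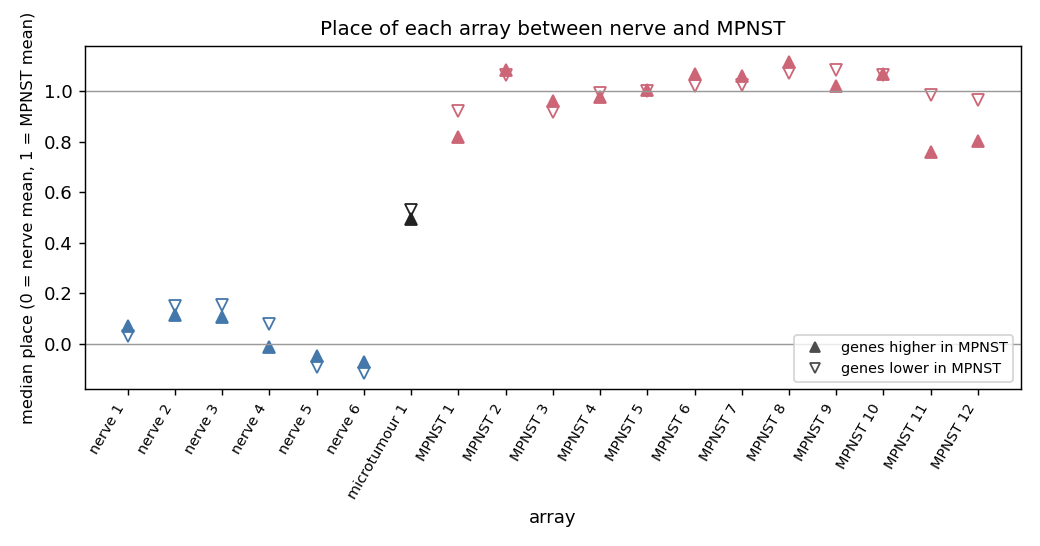
Median place of each array between the nerve mean (0) and the MPNST mean (1), separately for genes higher and genes lower in MPNST; for nerve and MPNST arrays the genes and means come from the other arrays. The microtumour lies at 0.49 for genes higher and at 0.53 for genes lower in MPNST, between the 6 nerve pools and the 12 MPNST.

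Males and females were compared within each tissue, since both sexes were profiled. No gene passed limma's test in either tissue. In MPNST (6 males, 6 females) 859 features had an unadjusted p under 0.05 where 589.8 are expected by chance, and the smallest adjusted p, that of Slco2b1, was 0.121. In nerve (3 male and 3 female pools) 503 features had an unadjusted p under 0.05 and the smallest adjusted p was 0.884. The count in nerve was also 0 with the signals of nerve 5 and nerve 6 exchanged. The difference between MPNST and nerve depended on sex for 0 features by limma's interaction test, with 143 at an unadjusted p under 0.05.

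The nerve pools of BDIV and BDIX were compared because the strains are the parents of the hybrids. The ribosomal protein gene Rpl30 was 22.7-fold higher in BDIV, by 4.51 ± 0.06 on the log2 scale (SE, 2 pools per strain). Its signal lay near the background in the BDIX pools (mean 7.39) and in the congenic pools (mean 7.27). Whether this signal reflects the abundance of the transcript was not tested. The glutathione peroxidase gene Gpx2 was 6.55-fold, Tmod1 5.56-fold, Ass1, an enzyme of the urea cycle, 5.36-fold, and Ttc9b 5.23-fold higher in BDIV. The haemoglobin genes Hba-a3, Hbb-b1 and Hbb were 20.2-fold, 8.26-fold and 5.15-fold lower, and Sema4g and Laptm5 were 5.96-fold and 4.88-fold lower. By limma's test 768 features were higher and 813 lower in BDIV at 2 residual degrees of freedom, but the count of 1581 fell to 0 without nerve 5 or without nerve 6 and to 467 without nerve 4, and it was 10 with the authors' values and 24 with nerve 5 and nerve 6 averaged. Those BDIV pools were closer to each other (SD of log2 differences 0.18) than the BDIX pools (0.51), and Hbb-b1, Hbb and Laptm5 did not pass when any 1 of the 4 pools was left out.

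The congenic strain, whose name gives BDIX as its background and BDIV as the donor, was compared with BDIX nerve. Setd5 was 3.23-fold higher in the congenic pools, by 1.69 ± 0.08 on the log2 scale (SE, 2 pools per strain), followed by Acsbg1 (2.59-fold), Amacr (2.40-fold), Ppp1r1b (2.39-fold) and Gga1 (2.36-fold). The cholesterol synthesis genes Idi1 and Fdps were 4.97-fold and 3.70-fold lower, Eif4a1, a translation factor, 4.41-fold, Pllp, a myelin gene, 4.12-fold, and Col4a1, a basement membrane collagen, 3.76-fold lower. By limma's test 133 features were higher and 172 lower, but no feature passed when any 1 of the 4 pools was left out, with the authors' values or with array weights. Both congenic pools were high-background arrays and both BDIX pools low-background arrays, so batch and strain cannot be told apart here. Chromosome 10 held 32 of the called genes among 743 tested, against 200 of 7815 on the other chromosomes (odds ratio 1.71, Fisher's exact p = 0.00874, two-sided, adjusted p = 0.184 over the chromosomes).

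Strain was tested in MPNST over 2 BDIV, 2 BDIX and 7 F1-hybrid tumours, and the differences here come from the fit with sex as a covariate. Cav1, a caveolar coat protein, was higher in BDIV than in BDIX tumours by 2.56 on the log2 scale, the MHC gene RT1-A3 by 2.72, Cbx7 by 2.44, Efemp1 by 2.29 and Slc29a1 by 2.16. The differences of BDIV from BDIX tumours were -2.66 for Kdelr3, -2.38 for Cdca8, -2.32 for Nipsnap3b, -2.30 for Nes and -2.22 for Cnrip1. By limma's F test 314 features differed (smallest adjusted p = 0.0115), but 5 with batch as a block. Both BDIV tumours were low-background and both BDIX tumours high-background arrays, so the batch term rests on MPNST 9, the 1 low-background hybrid. Over the 314 features the median absolute difference between BDIV and BDIX was 0.88 without and 0.73 with the block, the median SE 0.17 and 0.21, and the sign was the same for 307, so the drop was not resolved into a batch effect removed and precision lost. Those 5, named after their values were seen, were Cav1, Clic4, Cmpk1, Tuba1b and a probe without a symbol. Leaving out 1 tumour moved the count to 63 without MPNST 3, 77 without MPNST 4, 66 without MPNST 7, 89 without MPNST 8, 165 without MPNST 10, 182 without MPNST 11, 142 without MPNST 12 and 1189 without MPNST 9.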

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

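The interaction fits with a batch term and the other fits by background range were chosen only after the results were seen; the tests of liver-type transcripts were written before their results but after the pattern had been noticed.

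Among 109 values tested for an outlying nerve pool, 5 stood apart, about the 1 in 20 that chance gives, and each ratio is the gap to the nearest pool divided by the range of all 6. Vcan (0.666) and Prc1 (0.705) were highest in nerve 3, at 8.42 and 7.74 on the log2 scale where the other pools reached 7.90 and 7.43. C1qb (0.730) was lowest in nerve 4, at 8.17 where the others were at least 9.34. Ndufs1 (0.873) was lowest in nerve 3, at 10.73 where the others were at least 11.29. The interferon response list (0.782) was lowest in nerve 4, at -0.12 relative to the nerve mean, where the others were at least -0.01.

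The difference between MPNST and nerve was not the same in BDIV and BDIX for 12 named genes by limma's interaction test, in which 1499 features were called on 2 arrays per strain and tissue. Each value here is the difference in BDIV minus that in BDIX on the log2 scale, with sex as a covariate. It was 2.64 for Mbp, 1.497 for Sox10, 2.25 for Gsn, 1.72 for Maob and 1.15 for Mfap5, and these 5 genes were also called with a batch term. It was 1.95 for Dcn, 1.47 for Tjp1 (0.33 in BDIV and -1.10 in BDIX between group means), 1.98 for Cdkn1b and 2.79 for Hbb-b1, and -1.87 for Ccnb2, -1.09 for Ndufa10 and -0.19 for Cma1, none of which was called with a batch term. Their values with the batch term kept the sign, at 1.61, 1.19, 1.34, 3.43, -1.78, -0.74 and -0.18 in that order. With that term 794 features were called, 682 of them also without it; BDIV arrays of both tissues and BDIX nerve pools were low-background arrays, and BDIX tumours were high-background arrays. The batch term could be estimated only from the hybrid tumours, among which MPNST 9 alone was a low-background array, so a call with it does not exclude the background range.

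On MPNST 3 alone, 26 probes outside the detection filter were detected, where nerve 2 had 25 and the other nerve pools between 1 and 12. Several, named after their values were seen, were genes of secreted liver proteins and liver enzymes: Mup5 at 8.44 on the log2 scale, Alb at 8.01, Ambp at 7.96, Mup4 at 7.91, Ahsg at 7.55 and Cyp3a2 at 7.47. RNA from liver tissue in the sample may account for them, but on a separate list of 18 liver genes 50% (4 of the 8 detected on any array: Apoh, Fgg, Hpx and Cyp2e1) were highest in MPNST 3, on the bound of over 50% set for it, which leaves it open. Those 4 were near the background, at 7.52 to 7.75 in MPNST 3 and 7.42 to 7.74 on the next highest array. The other 4 were highest elsewhere, with Itih3 at 11.74 in nerve 2 and 8.10 in MPNST 3. Over the 8 detected genes the other high-background arrays differed from the low-background ones by -0.046. MPNST 3 exceeded the mean of the other arrays by 0.21. MPNST 3 was picked for its liver-type transcripts, so this outcome was largely fixed beforehand and decides nothing about the background range. A mixed-up sample was not tested, and no biological explanation was tested.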

How the results depend on the processing

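The fits by background range and the fits with nerve 5 and nerve 6 averaged or exchanged were chosen only after seeing the data. Under no setting was a called feature of MPNST against nerve called in the opposite direction, but counts moved. With median scaling 1399 features were higher in MPNST, 547 differed between microtumour and nerve, 740 between microtumour and MPNST, 202 between strains of MPNST and 110 between congenic and BDIX nerve. With the authors' values microtumour and MPNST differed in 712 features, BDIV and BDIX nerve in 10 and congenic and BDIX nerve in 0. Without background correction the nerve strain counts were 2887 and 1140, and without a detection filter 881 and 126, with 92 for MPNST strains. With array weights they were 600 for microtumour against MPNST, 567 for MPNST strains and 0 for congenic against BDIX nerve. The cause was not tested for these. Fewer arrays or a further criterion entered the next ones: a minimum difference of 1 left 666 higher and 777 lower, strains with nerve pools 1613 lower, high-background arrays 1726 higher, and low-background arrays 1230 higher, 994 lower, 146 for microtumour against nerve and 186 against MPNST. With sex and strain as covariates microtumour and MPNST differed in 559 features. With batch as a block 599 differed between microtumour and nerve and 5 between MPNST strains. Averaging nerve 5 and nerve 6 left 24 for BDIV against BDIX nerve and 0 for congenic against BDIX nerve.

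Of the 10 shifted lists, 1 (MAPK output) was shifted with an estimated correlation, while fry, which compares a list with no other genes, called 19. Leaving out each array in turn gave 2516 to 3007 higher and 2268 to 2523 lower features, 8 to 10 shifted lists, 312 to 437 features for microtumour against nerve and 267 to 395 against MPNST. For sex it gave 0 to 3 in MPNST (Efemp1, Tmem106c and a probe without a symbol without MPNST 1, C1qb and Rhbdf1 without MPNST 5, Slco2b1 without MPNST 7) and 0 to 0 in nerve. For strain it gave 63 to 1189 in MPNST, 0 to 2331 for BDIV against BDIX nerve (without nerve 5 and without nerve 3) and 0 to 0 for congenic against BDIX nerve.

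The values that changed sign were not past the test in either fit. Ngfr was at -0.30 with batch as a block and -1.21 in low-background arrays. List medians turned for adipocyte genes without a filter (0.013), endothelial genes with covariates (-0.029), with matched strains (-0.022) and in low-background arrays (-0.073), glycolysis genes without a filter (0.0058), in low-background arrays (0.056) and leaving out 1 array (0.0027), skeletal muscle genes with matched strains (-0.0022), and T and NK cell genes with the authors' values (-0.0095) and matched strains (-0.0035).

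The replicate numbers were not stated to pair tumours with pools, and 2 of 6 pairs deviated together (correlations from -0.30 to 0.21), so a replicate block has no basis in the design; it gave 2181 higher and 1807 lower features. Genes near the array background are limited by signal, as for Erbb2, Nf1, Kit and Cma1.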

Other observations

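The tests for a strain variant near the genes and of the background range in nerve were chosen only after their results were seen, and the other tests in this part were written before theirs, on patterns noticed in the same data. Genes named here were chosen after their values were seen.

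Muscle transcripts marked a pair of tumours. The skeletal muscle list lay 1.61 above the nerve mean on the log2 scale in MPNST 10 and 1.05 above it in MPNST 2, where the other MPNST lay between -0.07 and 0.11. Among its members, the sarcomere genes Acta1 and Tnnc2 varied most between the tumours, with SDs of 2.12 and 1.72 over the 12 MPNST.

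Interferon response genes divided the tumours. The list lay 0.63 to 1.04 above the nerve mean in MPNST 1, 3, 5, 11 and 12, and between -0.15 and 0.23 in the other MPNST. The microtumour was highest, at 1.30. Its level of the antiviral gene Mx1 was 11.05, where the nerve mean was 8.76 and the MPNST mean 8.95, and that of Irf7 was 10.17 against 7.97 and 8.82. The MHC class II genes RT1-Ba and RT1-Da were at 12.01 and 13.56 in the microtumour, above the MPNST means of 10.71 and 12.28, whereas RT1-DMb and RT1-DMa were at 9.97 and 8.48, below the means of 10.20 and 9.12.

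Whether chance could give such counts was examined by splitting the arrays in other ways. In 100 splits of the 18 arrays into 12 and 6, only the real one gave as many as 2906 higher or 2453 lower features, the highest others being 29 and 91, so chance was excluded for both. For the 10 shifted lists chance was not excluded, since 17 of the 100 splits gave at least as many and the highest other gave 13. For sex the real count was 0 in both tissues, which every split reaches (100 of 100 in MPNST and 10 of 10 in nerve), so the splits say nothing about chance there; the highest others were 8 and 718. In nerve, 2 splits gave 718 each, with both congenic pools on one side and both BDIV pools on the other, so with strain as a covariate these counts rest on nerve 3 against nerve 4, the BDIX pools. The background ranges were also argued against as the whole of the difference between MPNST and nerve, since the lower of the within-range shares of called features that kept their sign was 99.6%.

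Genes were sought that differed between BDIV and BDIX in the same direction in both tissues. A median of the F1-hybrid tumours between the parents was also required, so it is no result. The strains separated in the same direction in both tissues for 21.7% of features. Random orderings of independent arrays would give 5.56%, but all features share these arrays, and the BDIV and BDIX tumours lie in different background ranges. The comparison therefore does not measure a departure from chance. By these rules, and with a difference between strain means of at least 1 in each tissue, not adjusted for sex, 51 genes were chosen. Among them were Rpl30 (4.51 in nerve and 3.67 in MPNST, but near the background in BDIX nerve at 7.39), RT1-A3 (2.35 and 2.25), Sparc (-1.62 and -1.12) and Flna (-1.59 and -1.68). The congenic arrays were nearer BDIX for 40 of the 51 and nearer BDIV for 1, Msrb2. The congenic and BDIX tumours were high-background arrays and the BDIV tumours low-background arrays. In its tumour part this count therefore cannot tell strain from background range. A strain variant at or near the gene is a candidate explanation, but with a single gene on the BDIV side the test of 1 chromosome could show nothing (Fisher's exact p = 1 after adjustment). The division into background ranges does not account for the nerve part, since 0 of the 4 BDIV and BDIX pools were high-background arrays. Their raw 25th percentile was still 67.4 and 67.5 in the BDIV pools and 64.8 and 59.0 in the BDIX pools. A technical difference between these pools was therefore not excluded. For the MPNST part the background range may contribute, since the low-background hybrid MPNST 9 lay nearer the BDIV tumours for 64.7% of the genes and the high-background hybrids for 19.6% to 45.1%. It cannot be told apart from strain there, as the BDIV and BDIX tumours lie in different ranges.

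Pituitary hormone transcripts were high in MPNST 7. Prl, which encodes prolactin, was at 13.26 on the log2 scale in MPNST 7, 12.61 in nerve 2, 12.24 in nerve 4, 8.93 in MPNST 4 and 8.24 in nerve 3, and at most 7.63 elsewhere; Tshb was at 9.10 and Six6 at 8.83 in MPNST 7, and Pomc at 9.82 in nerve 3 and 9.59 in MPNST 7. RNA from pituitary tissue in the sample may account for these, but on a list of 13 pituitary genes, Pomc among them, 50% (4 of the 8 detected on any array: Lhb, Fshb, Pou1f1 and Ghrhr) were highest in MPNST 7, on the bound of over 50% set for it, and Cga was detected on no array. Those 4 were near the background, at 7.31 to 7.63 in MPNST 7 and 7.26 to 7.31 on the next highest array. The other high-background arrays did not share the excess of MPNST 7. They differed from the low-background ones by 0.0029 over the 8 detected genes, where MPNST 7 exceeded the mean of the other arrays by 0.11. MPNST 7 was picked for its high values, so this outcome was largely fixed beforehand. A mixed-up sample was not tested, and no biological explanation was tested.

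Brain was the other organ examined, in the microtumour. Of 12 brain neuron genes detected on any array, 0 (0%) were highest in the microtumour, where chance alone would give 5.26%. Some of them, such as Camk2a (7.27) and Neurod2 (7.26), were near the background there. A count of 0 is thus close to chance and does not exclude RNA from brain tissue as a source of its neuronal signal. Gria2, Gad1 and Kcnd2 were above both group means in the microtumour, at 9.03, 9.10 and 7.67, but reached 9.22, 11.15 and 7.88 on another array. A test against the background range was planned as well and was void, since the genes went both ways in the microtumour and their median excess of -0.0003 decides nothing (other low-background minus high-background arrays -0.013).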
